A study of Mus musculus with 99 samples.

How the data were processed

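The deposited values were bead-summary signals of Illumina MouseRef-8 arrays, one intensity per probe and array on a linear scale, which the authors had not normalized between arrays. BeadStudio was named in the submitters' processing notes without a version. The background setting and the scanner were not given in the sources used here. The 25697 probes carried signals from 65.5 to 50575 with 0 missing values, no 2 arrays held the same signals (0 identical pairs), and 0 columns of values per sample were left unused. A deposited series matrix held log2 values. These equalled the quantile-normalized log2 of the bead-summary signals with no background correction, with a largest difference of 4.97e-14 and a median of 7.30 in every column, so both deposited tables carried the same measurement.

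The intensities were corrected for background with the normexp model of limma 3.58.1 in R 4.3.3 (offset 50), taken to log2 and quantile-normalized over all 99 arrays. Detection p-values were not in the files used here, so the filter fixed for that case was applied: a probe was tested when its mean log2 value lay above the median of all probe means (the 50th percentile, 6.80 over the 99 arrays), which left 12848 probes. In the fits of 1 region the means were taken over the arrays of that region. A gene symbol was given to 23978 probes, several symbols to 0 probes and none to 1719 probes. Of the symbols, 23962 were matched through gene identifiers to the reference table and 0 changed. Genes were ordered along chromosome 11 with the mouse reference annotation, used for names and neighbour order only.

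Each region was fitted alone with limma (lmFit, eBayes with trend) on the 9 genotype-by-age groups with sex as a covariate. The fit over all regions held 27 groups, sex within region, and the animal as a random block because an animal gave up to 3 arrays (statmod 1.5.0). The consensus correlation within animals was 0.0582. Contrasts gave ages and regions equal weight. Values of p were two-sided and adjusted by Benjamini and Hochberg over all tested probes of a contrast, with 0.05 as the threshold. KO and Het contrasts shared the WT arrays, so their errors were not independent. The replicates were separate animals per the labels, and the number of arrays limited the precision. Slide was tested as a fixed and as a random block, because 6 slides held the 2-month arrays and 7 other slides held the 6- and 9-month arrays.

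Named genes followed a rule made before the data were examined, as were the contrasts, the 30 gene lists, the tests and most alternative settings. The rule took Grn in every contrast, up to 12 genes higher and 12 lower with the smallest p past the threshold for KO against WT over all regions, up to 5 each way within a region over all ages, and up to 3 each way in all other contrasts. It took up to 4 members of each list described, by the smallest p. A gene with several probes was named once by its probe with the smallest p, and a further probe of the gene that went the other way was given beside it, as were some that changed less. Probes without a symbol were counted and not named. Genes named outside the rule were the further called genes of chromosome 11, the clock genes Per1 and Per2, the markers used to check the region and sex labels, and list members given beside the first 4. These were chosen after their values were seen.

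The lists were homeostatic microglia, activated microglia, complement, lysosome, autophagy, inflammatory cytokines and NF-kB targets, interferon response and antigen presentation, astrocyte, reactive astrocyte, oligodendrocyte and myelin, oligodendrocyte precursor, endothelial and pericyte, neuron, glutamatergic synapse, GABAergic neuron, immediate early genes, Wnt signalling, cholesterol synthesis, mitochondrial respiratory chain, unfolded protein and heat shock response, genes near Grn on chromosome 11, choroid plexus, meninges and fibroblast, blood, striatum and hypothalamus, thalamus, cortex markers, hippocampus markers, cerebellum markers and sex-linked genes. A list was tested with at least 5 genes past the filter by cameraPR (limma, preset correlation 0.01) and adjusted over the lists of the contrast. The test was repeated with a correlation estimated from the residuals. Scores of 12 lists per animal were compared by a two-sided permutation test with 100000 resamples. Enrichment on a chromosome was tested with Fisher's exact test, two-sided, adjusted over the chromosomes.

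The alternative settings fixed then were no background correction, median scaling in place of quantile normalization, the series-matrix values, no probe filter, a stricter filter (75th percentile), no sex covariate, slide as a fixed or random block, a replicate block, only the arrays of the contrast, no animal block, array weights, each array or animal left out in turn, and for lists the estimated correlation, the mean t over probes and the lists without the genes near Grn. Added after the data were seen were the fits without 5 arrays of doubtful region, without the animal of doubtful sex, and with the mean of the cerebellum markers as a covariate, with and without the doubtful arrays. Other groupings of the same arrays were drawn up to 100 times (seed 20). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

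The fits were tested on simulated data with 200 of 12848 probes changed. Over all regions 91.0% of changes of 0.3 log2 and 100% of 0.6 were called, with 9 false calls among 203. Other groupings of real arrays gave up to 223, so the rates may not hold. Over all ages within cortex, hippocampus and cerebellum shares were 46.3%, 32.8% and 37.3% for 0.3 and 95.5%, 85.1% and 86.6% for 0.6. Shares were 17.9% and 89.6% in cortex at 2 months, and 2.99% and 23.9% in cerebellum at 6 months (78.8% for a change of 1).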

Results

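Gene expression was measured in 99 brain samples from 36 mice that carried 2 (WT), 1 (Het) or 0 (KO) working copies of Grn, the gene of progranulin, a secreted protein that also reaches lysosomes. Each genotype had 12 animals, 6 of them studied at 2 months, 3 at 6 months and 3 at 9 months. Of the animals, 27 gave cortex, hippocampus and cerebellum and 9 gave 2 of these regions. The arrays were 35 of cortex, 32 of hippocampus and 32 of cerebellum, or 32 WT, 33 Het and 34 KO arrays, in 27 groups of 2 to 6. The series design compared the genotypes in each region at each age. The median intensity of an array lay between 79.7 and 352. It was 79.7 to 114 in the 2-month arrays (median 90.1, n = 46) and 201 to 352 in the 6- and 9-month arrays (median 254, n = 53), which were on other slides. Medians by genotype were 89.1 in WT, 89.6 in Het and 90.8 in KO at 2 months. They were 258, 259 and 248.6 later. Correlations between arrays ran from 0.904 to 0.993.

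Grn itself was lower in every KO array than in every WT array. In cortex its mean log2 level was 9.11 ± 0.27 in WT (SD, n = 12), 8.39 ± 0.39 in Het (n = 11) and 6.08 ± 0.20 in KO (n = 12). The levels were 9.38 ± 0.25 (n = 10), 8.51 ± 0.41 (n = 11) and 6.12 ± 0.19 (n = 11) in hippocampus. They were 9.14 ± 0.34 (n = 10), 8.25 ± 0.41 (n = 11) and 6.18 ± 0.22 (n = 11) in cerebellum. KO arrays spanned 5.74 to 6.44, Het arrays 7.48 to 9.39 and WT arrays 8.40 to 9.69, so Het and WT overlapped. KO levels were near the floor of the arrays, which limits the size of fall that they measure. The median KO array had Grn brighter than 11.1% of probes, against 75.5% in Het and 83.3% in WT. Over all regions Grn fell by 3.09 ± 0.07 log2 in KO (34 of 34 arrays below the WT mean, limma adjusted p = 1.1e-51). In Het it fell by 0.85 ± 0.07 (33 of 33 arrays, adjusted p = 3.1e-15). Within the 12 slides that held both genotypes the KO minus WT difference lay between -3.48 and -2.73, with a median of -3.12.

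**Figure D1:**
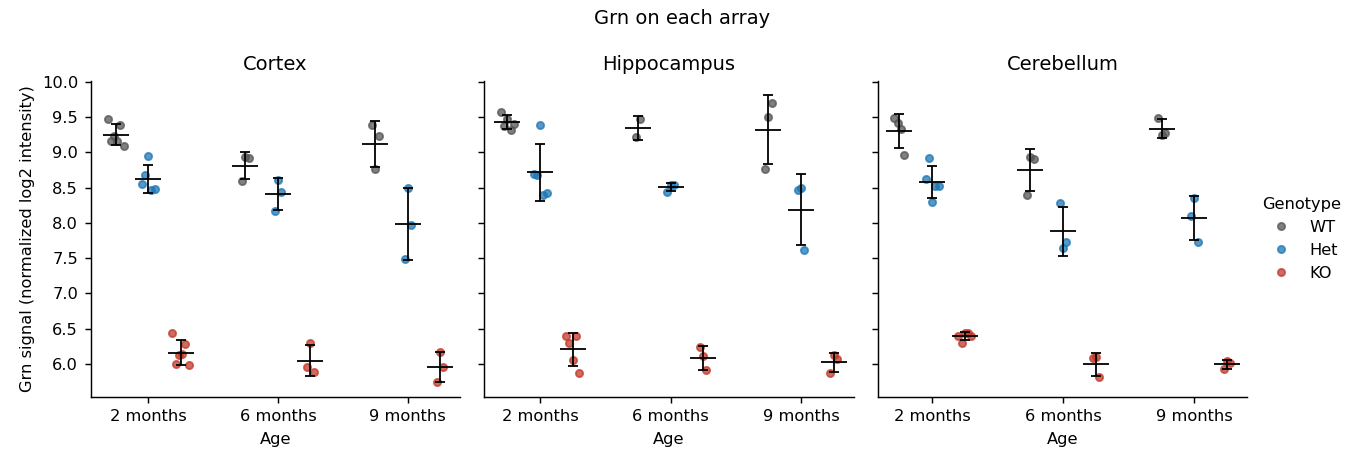
Grn level (log2 intensity) in each of the 99 arrays by region, genotype and age; points are arrays and bars the group mean with its SD. The highest KO array stood at 6.44 and the lowest WT array at 8.40.

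Over the 3 regions together, genes of microglia and of complement were higher in KO than in WT, and genes on the chromosome of Grn differed in both directions. Over all regions and ages 85 probes changed between 34 KO and 32 WT arrays, 62 higher and 23 lower. They stood for 75 genes and 3 probes without a symbol, and 694 probes had an unadjusted p under 0.05. Lysozyme, the bacteria-lysing enzyme of phagocytes, rose through both its genes. Lyz1 rose by 1.17 ± 0.12 log2 (higher in 34 of 34 KO arrays) and Lyz2 by 1.08 ± 0.12 (33 of 34, with 0.74 on its other probe). The microglial receptor Trem2 rose by 0.58 ± 0.07 and its signalling adaptor Tyrobp by 0.56 ± 0.06 (33 of 34 each). Gpnmb, a membrane glycoprotein of loaded phagocytes, rose by 0.84 ± 0.12 (29 of 34). The complement component C4b rose by 0.68 ± 0.08 (31 of 34) and Gfap, the intermediate filament of astrocytes, by 0.68 ± 0.10 (26 of 34). Adjusted p for these 7 genes ran from 1.9e-11 to 9.1e-07.

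Of the 23 genes other than Grn that the rule named in this contrast, 17 lie on chromosome 11 with Grn, among them Gfap, 7 tested genes from Grn. Higher in KO were Lsm12 by 0.67 ± 0.04 (34 of 34 arrays, adjusted p = 5.6e-21), and the Wnt receptor Fzd2 by 0.60 ± 0.06 (33 of 34). So were Cuedc1 by 0.64 ± 0.09 (34 of 34), Nle1 by 0.50 ± 0.06 (33 of 34) and the kinase gene Prkca by 0.43 ± 0.06 (33 of 34). Lower were the keratin gene Krt12 by 1.31 ± 0.15 (32 of 34), Rapgefl1 by 1.17 ± 0.10 (34 of 34), and 4933427D14Rik by 1.00 ± 0.15 (32 of 34). Cybc1 fell by 0.46 ± 0.10 (30 of 34), the mitochondrial ribosome gene Mrps23 by 0.44 ± 0.06 (34 of 34) and Rdm1 by 0.41 ± 0.05 (34 of 34). Fam171a2, the neighbour of Grn, fell by 0.38 ± 0.05 (31 of 34) and Arhgap27 by 0.30 ± 0.05 (31 of 34). The diacylglycerol kinase gene Dgke fell by 0.28 ± 0.05 (32 of 34), Rsad1 by 0.27 ± 0.06 (29 of 34) and Stxbp4 by 0.24 ± 0.05 (30 of 34). Their adjusted p ran up to 0.0059. A further probe differed for Lsm12 (0.12), Rapgefl1 (0.15) and Stxbp4 (0.14). Of the 85 probes 45 kept their call with slide as a fixed block, and 77 did without the 5 arrays of doubtful region.

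**Figure D2:**
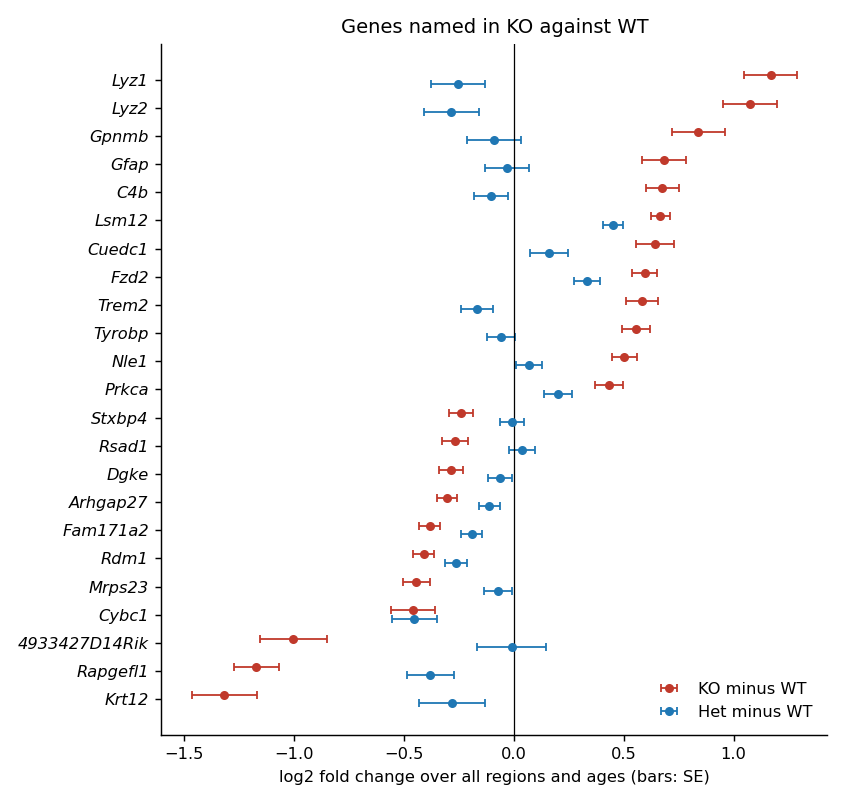
Change in log2 with its SE for the 23 named genes other than Grn, KO against WT (34 and 32 arrays) and Het against WT (33 and 32 arrays), over all regions and ages. Lyz1 stood at 1.17 in KO, and Lsm12 at 0.67 in KO and 0.45 in Het.

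The gene lists placed these changes in groups. Of 20 tested genes of activated microglia 8 rose and 0 fell in KO (15 and 0 adjusted over the list alone, median 0.23, adjusted p = 4.8e-39), among them Lyz1, Lyz2, Tyrobp and Trem2. Of 8 complement genes 4 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.31, adjusted p = 3.6e-18), but without a probe filter, which adds dim genes, the median was -0.0028. These were C4b and the genes of the starting component of the classical pathway, C1qa by 0.36 ± 0.05, C1qb by 0.44 ± 0.09 and C1qc by 0.47 ± 0.08. Of 41 lysosome genes 7 rose and 0 fell (9 and 1 adjusted over the list alone, median 0.06, adjusted p = 2.4e-10). The mannosidase Man2b1 was higher by 0.31 ± 0.05, the glucuronidase Gusb by 0.23 ± 0.05, the hexosaminidase Hexa by 0.21 ± 0.05 and the membrane protein Cd63 by 0.28 ± 0.06. Homeostatic microglia genes had 3 of 17 higher and 0 lower (7 and 0 adjusted over the list alone, median 0.14, adjusted p = 2.7e-09). Fcrls stood at 0.32 ± 0.06, Laptm5 at 0.38 ± 0.08 and Aif1 at 0.22 ± 0.06. Reactive astrocyte genes had Gfap, which lies near Grn, C4b and Aspg (0.23 ± 0.06) as 3 of 14 higher and 0 lower (4 and 0 adjusted over the list alone, median 0.10, adjusted p = 5.25e-10). All 5 calls held with an estimated correlation, at adjusted p from 3.9e-10 to 0.029. Within the 12 slides the activated microglia list was higher in KO in 12 (0.08 to 0.49), complement and reactive astrocyte in 11, lysosome in 10 and homeostatic microglia in 9. Blocking on slide gave medians of 0.21 for activated microglia, 0.29 for complement and 0.11 for reactive astrocyte.

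Of the other lists only oligodendrocyte and myelin passed between KO and WT. It had 0 of 14 genes past the threshold and a median of -0.08 (adjusted p = 0.012, but adjusted p = 0.75 with an estimated correlation), and it was higher in KO within 3 of 12 slides. Among lists that did not pass, single members rose in inflammatory cytokines and NF-kB targets (10 genes, median 0.04, adjusted p = 0.246, Tlr2 higher by 0.26 ± 0.05), astrocyte (17, 0.02, 0.0823, Gfap). They also rose in Wnt signalling (22, 0.0019, 0.421, Fzd2) and hippocampus markers (11, 0.04, 0.369, Spink8 higher by 0.62 ± 0.16). No gene passed in the other lists, 0 each by limma, with 694 probes of all genes at an unadjusted p under 0.05. Their medians and adjusted p were -0.000398 and 0.613 for autophagy (19 genes), and -0.01 and 0.421 for interferon response and antigen presentation (17). They were 0.04 and 0.421 for oligodendrocyte precursor (6), -0.01 and 0.421 for endothelial and pericyte (17), and -0.01 and 0.381 for neuron (20). Synaptic and interneuron lists gave -0.02 and 0.421 for glutamatergic synapse (12) and 0.07 and 0.495 for GABAergic neuron (13). They were 0.14 and 0.306 for immediate early genes (16), and -0.00394 and 0.421 for cholesterol synthesis (15). Those of the mitochondrial respiratory chain list were 0.00581 and 0.974 (27, mean -0.00292) and those of the unfolded protein and heat shock response -0.00682 and 0.495 (16). Markers of neighbouring tissue gave 0.00928 and 0.974 for choroid plexus (12), 0.03 and 0.613 for meninges and fibroblast (10), and 0.02 and 0.613 for striatum and hypothalamus (12). They gave 0.06 and 0.613 for thalamus (10), -0.02 and 0.306 for cortex markers (12) and -0.03 and 0.381 for cerebellum markers (13). The sex-linked list gave 0.04 and 0.802 (7 genes, mean -0.00492), and the blood list, with 3 genes past the filter of 10 measured, was not tested.

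Scores per animal counted each animal once. Between 12 KO and 12 WT animals the activated microglia score was higher by 0.347 ± 0.0439 (SE, permutation p = 2e-05, adjusted over 12 scores 0.00024) and complement by 0.296 ± 0.0663 (permutation p = 0.00046). It was higher for reactive astrocyte by 0.173 ± 0.0484 (permutation p = 0.00169), homeostatic microglia by 0.128 ± 0.0424 (p = 0.0105) and lysosome by 0.0679 ± 0.0141 (p = 0.001). The astrocyte score was higher by 0.0499 ± 0.0217 (permutation p = 0.0229) and that of the genes near Grn by 0.0424 ± 0.0112 (permutation p = 0.00346). These 7 passed after adjustment. Differences of -0.0868 ± 0.0622 for oligodendrocyte and myelin, -0.257 ± 0.211 for blood, 0.0284 ± 0.0589 for meninges, 0.0116 ± 0.0927 for choroid plexus and -0.0325 ± 0.0469 for neuron did not, with permutation p from 0.0556 to 0.587.

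Along chromosome 11 the called genes lay on both sides of Grn. Of 778 tested genes of that chromosome other than Grn, 27 changed in KO (3.47%, against 0.572% on the other chromosomes, odds ratio 6.25, Fisher's exact adjusted p = 6.2e-10). Of the 100 tested genes nearest to Grn 11 were called, of the nearest 200 there were 14, and of the nearest 378 there were 25. The called genes were 11 higher and 16 lower. Among those outside the rule were Fn3krp, a kinase of glycated proteins, higher by 0.78 ± 0.12, the growth factor antagonist Nog at 0.28 ± 0.06, the transcription factor Etv4 at 0.26 ± 0.06 and St6galnac2, lower by 0.30 ± 0.07. The fixed list of genes near Grn had 4 of 40 genes higher and 3 lower (8 and 4 adjusted over the list alone), with a median of 0.03 and adjusted p = 0.0823. It passed with slide as a fixed block (adjusted p = 0.038), without the arrays of doubtful region (0.0496) and without the animal of doubtful sex (0.0499).

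**Figure D3:**
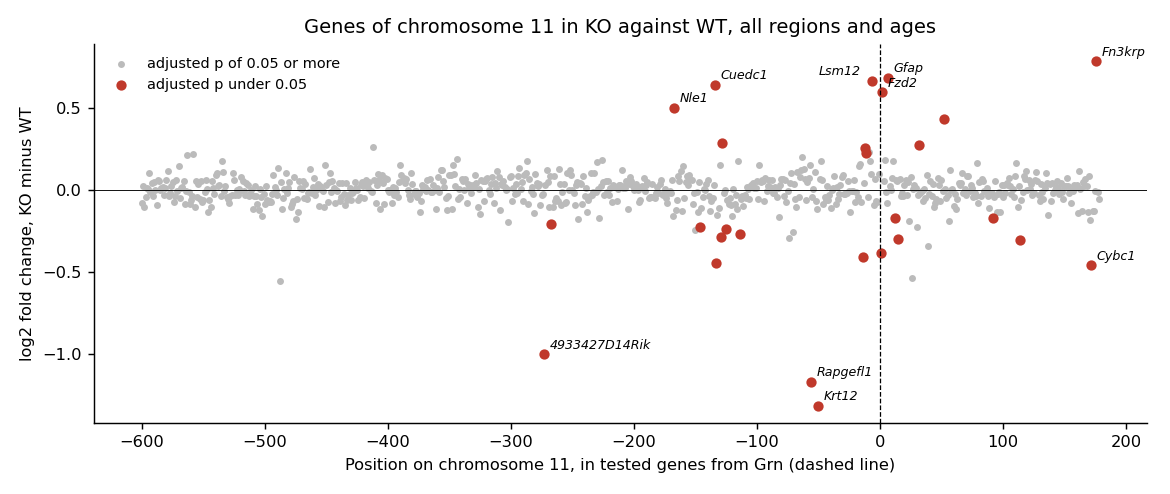
Change in log2 between KO and WT over all regions and ages for the tested genes of chromosome 11, by position in tested genes from Grn; red points have adjusted p under 0.05. Of 778 genes other than Grn 27 were called, and Grn stood at -3.09.

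Between Het and WT 19 probes differed over all regions and ages, 9 higher and 10 lower in Het, for 13 genes and 6 probes without a symbol, with 485 probes at an unadjusted p under 0.05. Next to Grn, the genes of chromosome 11 Lsm12 (0.45 ± 0.04, 33 of 33 arrays, adjusted p = 5.3e-12), Fn3krp (0.89 ± 0.12, 29 of 33, 6.7e-07) and Fzd2 (0.33 ± 0.06, 31 of 33, 0.00037) rose. Lgals3bp, a secreted partner of galectins, fell by 0.49 ± 0.08 (29 of 33, adjusted p = 0.00037) and Rdm1 by 0.26 ± 0.05 (29 of 33, 0.0030). On chromosome 11 6 of 778 genes were called (0.771%, Fisher's exact adjusted p = 0.0051). Of the 19 probes 8 kept their call with slide as a fixed block, and median scaling gave 41 calls, 23 higher and 18 lower.

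No microglial list was higher in Het. The activated microglia list had a median of -0.07 (0 of 20 past the threshold, adjusted p = 0.00012, but adjusted p = 0.14 with an estimated correlation), the lysosome list one of -0.03 (0 of 41, 0.0035, adjusted p = 0.13 with an estimated correlation) and the homeostatic list one of -0.04 (0 of 17, 0.021, adjusted p = 0.58 with an estimated correlation). Interferon response and antigen presentation genes were lower as a group, with a median of -0.17, 0 of 17 past the threshold over all genes and 0 higher and 6 lower adjusted over the list alone (adjusted p = 8.8e-14, adjusted p = 0.0081 with an estimated correlation). Its members included B2m, the light chain of class I molecules, at -0.26 ± 0.08 (lower in 23 of 33 arrays), Ifit3 at -0.33 and Oasl2 at -0.27. Complement had a median of -0.11, with Cd59a, an inhibitor of the membrane attack complex, at -0.49 (0 of 8 past the threshold, 0 higher and 1 lower adjusted over the list alone, adjusted p = 4.7e-06, adjusted p = 0.047 with an estimated correlation). Immediate early genes had a median of 0.27, with Fos at 0.72 ± 0.20 and Dusp1 at 0.44 ± 0.12 (0 of 16 past the threshold, 3 and 0 adjusted over the list alone, adjusted p = 1.4e-11, but adjusted p = 0.062 with an estimated correlation). Choroid plexus genes had a median of -0.18 (adjusted p = 0.00016, but adjusted p = 0.45 with an estimated correlation) and sex-linked genes one of 0.05 (0.032, adjusted p = 0.13 with an estimated correlation).

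KO and Het animals differed more than KO and WT animals did in number of calls, a difference that was not tested. There were 135 probes, 114 higher and 21 lower in KO, for 115 genes and 8 probes without a symbol, with 1054 at an unadjusted p under 0.05. Lyz1 was higher by 1.42 ± 0.12 and Lyz2 by 1.36 ± 0.12 (34 of 34 arrays each, 0.79 on the other Lyz2 probe) and Trem2 by 0.75 ± 0.07 (31 of 34). Grn was lower by 2.24 ± 0.07 (34 of 34), Krt12 by 1.04 ± 0.15 (31 of 34) and Rapgefl1 by 0.79 ± 0.10 (32 of 34, 0.07 on its other probe). Activated microglia genes were higher in 13 of 20 (15 adjusted over the list alone, median 0.31, adjusted p = 1.4e-56), complement in 5 of 8 (8 adjusted over the list alone, median 0.41, 2.2e-34), lysosome in 8 of 41 (16 adjusted over the list alone, median 0.10, 3.1e-18) and homeostatic microglia in 6 of 17 (11 adjusted over the list alone, median 0.17, 4.3e-15). Reactive astrocyte genes were higher in 4 of 14 (median 0.15, 7.2e-13), and these 5 lists had 0 genes lower and held with an estimated correlation at adjusted p of 0.0016 or less. Interferon response genes had 3 higher, B2m, Cd74 and H2-Ab1 (median 0.09, adjusted p = 2.7e-06, but adjusted p = 0.088 with an estimated correlation). Of the 135 probes 121 kept their call with slide as a fixed block, and 97 did without the animal of doubtful sex.

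In cortex KO changed 25 probes over all ages, 16 higher and 9 lower (12 KO and 12 WT arrays, 1035 probes at an unadjusted p under 0.05). With median scaling there were 26 higher and 8 lower, and with slide as a fixed block 9 probes. Lyz1 rose by 1.17 ± 0.14, Lyz2 by 0.84 ± 0.11, Lsm12 by 0.71 ± 0.08 and Fzd2 by 0.66 ± 0.07 (12 of 12 arrays each), and C4b by 0.65 ± 0.09 (11 of 12). Grn fell by 3.00 ± 0.10, and Krt12 fell by 1.69 ± 0.17, Rapgefl1 by 1.25 ± 0.15 and the adaptor gene Stac2 by 0.50 ± 0.07 (12 of 12 each). Myl4, a myosin light chain on the cortex marker list, fell by 0.96 ± 0.13 (11 of 12). Adjusted p for these 10 genes was at most 0.00014. Activated microglia genes were higher in 4 of 20 (10 adjusted over the list alone, median 0.21, adjusted p = 1.7e-18), complement in 1 (6 adjusted over the list alone, median 0.28, 2.9e-08), lysosome in 1 (7 adjusted over the list alone, median 0.07, 0.00066) and reactive astrocyte in 1 (2 adjusted over the list alone, median 0.10, 0.00050). Cortex markers had 0 higher and 1 lower, Myl4 (median -0.11, adjusted p = 0.00025). These 5 calls held with an estimated correlation, at adjusted p from 1.2e-07 to 0.049, but reactive astrocyte lost its call with slide as a fixed block (adjusted p = 0.168). With the preset correlation alone, homeostatic microglia (median 0.09), thalamus (0.27) and cerebellum markers (0.16) were higher and neuron (-0.04) and glutamatergic synapse genes (-0.12) lower (adjusted p from 0.027 to 0.035, but adjusted p from 0.107 to 0.651 with an estimated correlation).

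Het cortex had 4 probes, with Lsm12 (0.51 ± 0.08, adjusted p = 0.0013), Fzd2 (0.43 ± 0.07, 0.0063) and Ttc39a (0.33 ± 0.06, 0.048) higher and Grn (-0.71 ± 0.10, 0.0013) lower in 11 of 11 arrays each. With slide as a fixed block there were 10 probes, and Grn (-0.68, adjusted p = 0.103) was not among them. By age, KO changed 15 probes at 2 months (8 higher, 7 lower), 1 at 6 months (0 higher, 1 lower) and 7 at 9 months (4 higher, 3 lower), with 859, 1011 and 224 at an unadjusted p under 0.05. With median scaling these were 22 higher and 4 lower, 2 and 1, and 4 and 1, and at 2 months that scaling raised the median of all tested probes by 0.16. At 2 months Fzd2 rose by 0.86 ± 0.09, Nle1 by 0.68 ± 0.11 and Lsm12 by 0.65 ± 0.10, and Grn fell by 3.09 ± 0.13, Krt12 by 1.61 ± 0.23 and Myl4 by 1.33 ± 0.18 (6 of 6 arrays each). At 6 months Grn was the gene called (-2.74 ± 0.20, 3 of 3). At 9 months Lyz1 rose by 1.40 ± 0.27, Lyz2 by 1.13 ± 0.21 and Lsm12 by 0.90 ± 0.14 (-0.01 on another probe), and Grn fell by 3.18 ± 0.19, Krt12 by 1.85 ± 0.33 and Fam171a2 by 0.59 ± 0.11 (3 of 3 each). Limma called 0 probes at 9 months with slide as a fixed block. Het changed 1 probe at 2 months, the transcription factor gene Prox1 (0.48 ± 0.09, 5 of 5, a call lost in most alternative fits), 0 at 6 months by limma (1415 at an unadjusted p under 0.05) and Grn at 9 months (-1.14 ± 0.19, 3 of 3, adjusted p = 0.016). Grn stood at -0.62 ± 0.14 in Het at 2 months (adjusted p = 0.199) and at -0.38 ± 0.20 at 6 months (0.486), which did not pass in limma.

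In hippocampus KO changed 13 probes over all ages, 9 higher and 4 lower (11 KO and 10 WT arrays, 258 at an unadjusted p under 0.05). With median scaling there were 15 higher and 3 lower, and with slide as a fixed block 1 probe. Gfap rose by 0.74 ± 0.13 (8 of 11 arrays), Lsm12 by 0.69 ± 0.06 (-0.06 on another probe), Fzd2 by 0.67 ± 0.09, Prkca by 0.53 ± 0.09 and C1qc by 0.47 ± 0.09 (11 of 11 each). Grn fell by 3.26 ± 0.13, and Krt12 fell by 1.84 ± 0.23, Rapgefl1 by 1.22 ± 0.16 (0.14 on its other probe) and Rdm1 by 0.50 ± 0.10 (11 of 11 each). Activated microglia genes were higher in 2 of 21 (5 adjusted over the list alone, median 0.25, adjusted p = 1.6e-19), homeostatic microglia in 1 of 18 (5 adjusted over the list alone, median 0.17, 3.3e-10), complement in 1 of 8 (4 adjusted over the list alone, median 0.26, 4.1e-10), reactive astrocyte in 1 (2 adjusted over the list alone, median 0.13, 3.3e-07) and astrocyte in 1 (median 0.11, 0.00036). Lysosome genes moved with 0 members past the threshold (median 0.04, adjusted p = 5.3e-05, 258 probes at an unadjusted p under 0.05 in limma). These 6 calls held with an estimated correlation, at adjusted p from 0.00024 to 0.033. With slide as a fixed block lysosome (adjusted p = 0.221) and reactive astrocyte (0.118) lost theirs. Myelin genes were lower (median -0.11, adjusted p = 0.0088, but adjusted p = 0.574 with an estimated correlation), and at -0.65 with slide as a fixed block (adjusted p = 7.4e-13). Hippocampus markers were higher (0.11, adjusted p = 0.044, but adjusted p = 0.433 with an estimated correlation).

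Het hippocampus had 2 probes, Lsm12 (0.51 ± 0.06) and Grn (-0.90 ± 0.13, adjusted p = 0.0020), in 11 of 11 arrays each, against 2 higher and 1 lower with median scaling. With slide as a fixed block limma called 0 probes, and Grn stood at -0.71 (adjusted p = 1.00). By age KO changed 7 probes at 2 months (3 higher, 4 lower), 1 at 6 months (Grn, -3.29 ± 0.27, 3 of 3 arrays) and 4 at 9 months (1 higher, 3 lower), with 485, 804 and 247 at an unadjusted p under 0.05. With median scaling the 6-month count was 3 higher and 3 lower, and at 2 months that scaling raised the median of all tested probes by 0.11. At 2 months Fzd2 rose by 0.92 ± 0.12, Nle1 by 0.87 ± 0.13 and Lsm12 by 0.67 ± 0.08 (-0.14 on another probe), and Grn fell by 3.22 ± 0.18, Krt12 by 1.90 ± 0.31 and Rapgefl1 by 1.51 ± 0.22 (5 of 5 each, 0.10 on its other probe). At 9 months Lsm12 rose by 0.77 ± 0.11 and Grn fell by 3.28 ± 0.24, Krt12 by 2.21 ± 0.41 and Rapgefl1 by 1.54 ± 0.29 (3 of 3 each). Limma called 0 probes at 6 and at 9 months with slide as a fixed block. Het changed 1 probe at 2 months, Lsm12 (0.50 ± 0.08, 5 of 5, a call lost with median scaling or slide as a fixed block), and 0 at 6 and 9 months by limma (170 and 419 at an unadjusted p under 0.05). Grn in Het stood at -0.71 ± 0.18, -0.87 ± 0.27 and -1.13 ± 0.23 at 2, 6 and 9 months and did not pass.

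In cerebellum KO changed 16 probes over all ages, 13 higher and 3 lower, for 14 genes and 1 probe without a symbol (11 KO and 10 WT arrays, 914 at an unadjusted p under 0.05). With slide as a fixed block 3 probes were called. Lyz1 rose by 1.22 ± 0.15 and Lsm12 by 0.60 ± 0.08 (11 of 11 arrays each), Lyz2 by 1.10 ± 0.13 and C4b by 0.74 ± 0.13 (10 of 11 each) and Tyrobp by 0.63 ± 0.11 (11 of 11). Grn fell by 2.99 ± 0.09, Rapgefl1 by 1.04 ± 0.19 (0.41 on its other probe) and Rdm1 by 0.40 ± 0.08 (11 of 11 each). Activated microglia genes were higher in 6 of 20 (10 adjusted over the list alone, median 0.27, adjusted p = 1.4e-22), complement in 1 of 8 (6 adjusted over the list alone, median 0.39, 8.3e-10) and reactive astrocyte in 1 of 15 (4 adjusted over the list alone, median 0.12, 5.0e-06). Lysosome genes moved with 0 of 42 past the threshold over all genes and 5 higher adjusted over the list alone (median 0.08, adjusted p = 1.3e-05). These 4 calls held with an estimated correlation at adjusted p from 4.1e-05 to 0.017. Homeostatic microglia genes had a median of 0.22 (0 past the threshold, 2 adjusted over the list alone, adjusted p = 1.3e-05, but adjusted p = 0.511 with an estimated correlation) and cerebellum markers one of -0.33 (adjusted p = 0.0018, but adjusted p = 0.731 with an estimated correlation). The array labelled cerebellum of KO replicate 1 at 2 months lacked cerebellum markers (7.73).

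Het cerebellum had Grn as its 1 probe over all ages (-0.93 ± 0.10, 11 of 11 arrays). Interferon response genes were lower there as a group (median -0.22, 0 past the threshold, 0 higher and 4 lower adjusted over the list alone, adjusted p = 1.6e-11, adjusted p = 0.015 with an estimated correlation). By age KO changed 3 probes at 2 months (1 higher, 2 lower), 359 at 6 months (138 higher, 221 lower) and 7 at 9 months (6 higher, 1 lower), with 691, 2808 and 179 at an unadjusted p under 0.05. With median scaling the 2-month count was 0 higher and 1 lower and the 6-month count 40 higher and 129 lower. At 2 months Nle1 rose by 0.92 ± 0.16 and Grn fell by 2.93 ± 0.14 and the receptor gene Gpr162 by 0.66 ± 0.12 (5 of 5 each, with Gpr162 at 0.16 on its other probe). At 9 months Lyz1 rose by 1.86 ± 0.28, Lyz2 by 1.79 ± 0.24 and the galectin gene Lgals3 by 1.12 ± 0.19, and Grn fell by 3.39 ± 0.17 (3 of 3 each). The activated microglia list at that age had 4 genes higher and 0 lower (7 and 0 adjusted over the list alone, median 0.27, adjusted p = 5.4e-34, adjusted p = 8.4e-08 with an estimated correlation). At 6 months, beside Grn (-2.65 ± 0.18), the translation factor gene Eif3d rose by 0.94 ± 0.18, Mgst3 by 0.78 ± 0.15 and Ap1b1 by 0.75 ± 0.14, while the neuronal RNA-binding gene Elavl4 fell by 1.18 ± 0.22 (0.01 on its other probe) and Mfap1b by 0.84 ± 0.16 (3 of 3 each, adjusted p = 0.031). With slide as a fixed block or without the sex covariate 1 probe was left of the 359. At that age cerebellum markers had a median of -0.73 (adjusted p = 0.011, but adjusted p = 0.707 with an estimated correlation). Het changed 0 probes at 2 and 6 months by limma (224 higher and 159 lower at 2 months and 333 in all at 6 months at an unadjusted p under 0.05) and Grn at 9 months (-1.27 ± 0.17, 3 of 3, adjusted p = 0.00080). Grn in Het stood at -0.75 ± 0.14 and -0.77 ± 0.18 at 2 and 6 months and did not pass.

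**Figure D4:**
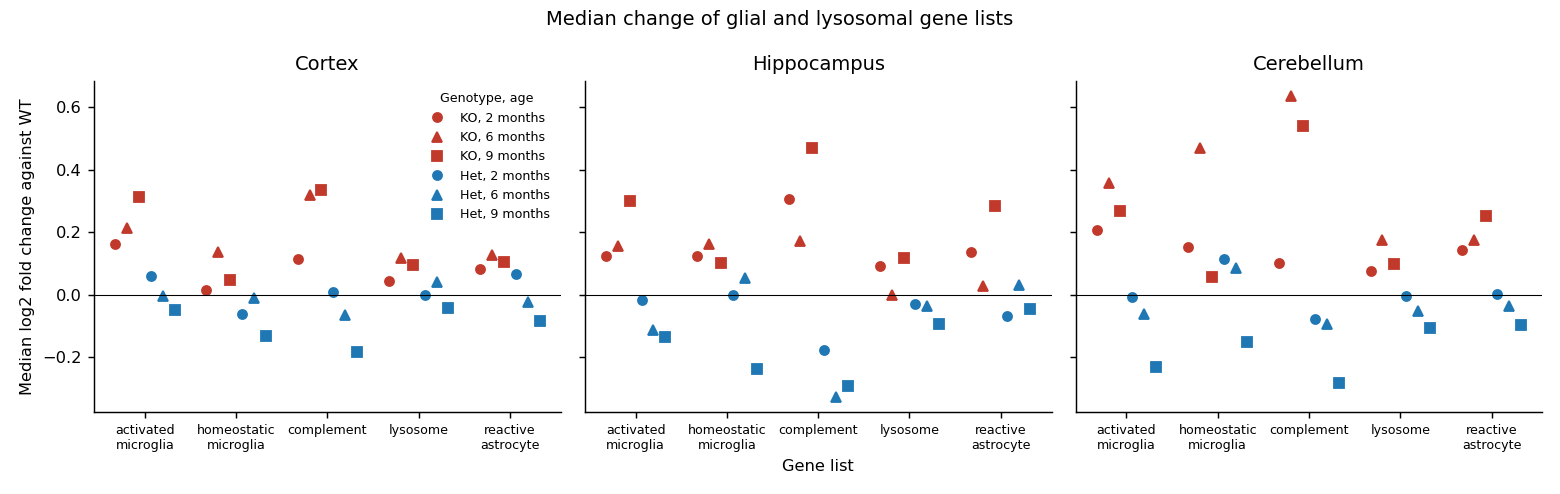
Median change in log2 of 5 gene lists against WT in each region at each age, KO in red and Het in blue, with circles for 2, triangles for 6 and squares for 9 months. The activated microglia list in KO stood at 0.31 in cortex, 0.30 in hippocampus and 0.27 in cerebellum at 9 months.

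Whether the effect of KO differed between regions was tested directly. Limma called 0 probes for cortex against cerebellum, cortex against hippocampus and hippocampus against cerebellum, with 533, 396 and 728 probes at an unadjusted p under 0.05. Array weights gave 210, 8 and 9. The effect of KO at 9 against 2 months likewise gave 0 probes in cortex, hippocampus and cerebellum by limma, with 218, 290 and 333 at an unadjusted p under 0.05. The activated microglia list had medians in KO against WT of 0.16, 0.21 and 0.31 at 2, 6 and 9 months in cortex, of 0.13, 0.16 and 0.30 in hippocampus and of 0.21, 0.36 and 0.27 in cerebellum. Tissue markers moved further in KO cortex at 2 months and KO cerebellum at 6 months, none past the threshold with an estimated correlation. Calls of the activated microglia list with an estimated correlation held at all 3 ages in cortex (adjusted p = 0.031, 0.047 and 2.6e-08) and at 9 months in hippocampus (0.0022) and cerebellum. At 9 months WT was all male, and KO held 1 labelled female and 1 animal of doubtful sex. Sex was thus not fully told apart from KO there. The list's KO effect differed by 0.16 to 0.22 between 9 and 2 months. It passed in each region, but not with an estimated correlation (adjusted p of 0.109 or more). Median scaling lowered the median of all tested probes in this contrast by 0.19 in cortex and 0.20 in hippocampus.

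Age 9 against 2 months changed 8497 probes in cortex (4010 higher, 4487 lower), 6910 in hippocampus (3426 higher, 3484 lower) and 7586 in cerebellum (3831 higher, 3755 lower). Median scaling gave 8087 higher and 1451 lower, 8974 and 562, and 9580 and 450, and it moved the median of all tested probes by 0.37, 0.48 and 0.56. No slide held both ages, so age and slide could not be told apart here. The actin-binding gene Pfn1 was higher by 1.35 ± 0.06 in cortex, 1.51 ± 0.09 in hippocampus and 1.48 ± 0.07 in cerebellum (1.90, 2.21 and 2.26 with median scaling, 0.17 on its other probe in cortex). In cortex Hnrnpa1 was higher by 1.68 ± 0.09 and Ociad2 by 1.44 ± 0.08. Npm3-ps1 was lower by 1.72 ± 0.08, Polr2i by 1.03 ± 0.05 and Stx5a by 0.93 ± 0.05 (0.15 on its other probe). With median scaling these 3 were -1.39, -0.55 and -1.09. In hippocampus Rpl7a was higher by 1.42 ± 0.09 and Pebp1 by 1.50 ± 0.10. Stx5a was lower by 0.91 ± 0.05 (0.19 on its other probe), Appbp2 by 0.92 ± 0.06 and Zc3h3 by 1.11 ± 0.07. Median scaling gave -0.82, -0.66 and -0.40. In cerebellum M6pr was higher by 1.34 ± 0.07 (0.39 on its other probe) and Uba3 by 1.39 ± 0.08. Npm3-ps1 was lower by 1.68 ± 0.07, Trub2 by 1.57 ± 0.09 and Plpp3 by 1.03 ± 0.05 (higher by 0.94 on its other probe). These falls were -0.93, -1.57 and -1.43 with median scaling. Activated microglia genes were higher in 14 of 20 and lower in 2 in cerebellum (median 0.58, adjusted p = 0.0046, but adjusted p = 0.613 with an estimated correlation). In cortex they were higher in 13 and lower in 2 (median 0.33, 0.025, 0.351 with an estimated correlation). Myelin genes there were higher in 2 and lower in 10 (median -0.59, 0.0056, 0.533 with an estimated correlation).

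Ages 9 and 6 months shared slides, and limma called 0 probes between them in cortex, hippocampus and cerebellum, with 346, 322 and 1177 at an unadjusted p under 0.05. Activated microglia genes had medians of 0.07 in cortex (adjusted p = 0.00018, but adjusted p = 0.086 with an estimated correlation) and 0.21 in cerebellum (1.6e-06, adjusted p = 0.277 with an estimated correlation). Complement genes had a median of 0.18 in cortex (0.00017, adjusted p = 0.086 with an estimated correlation) and myelin genes one of -0.25 in hippocampus (0.00021, adjusted p = 0.464 with an estimated correlation).

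In WT animals cerebellum against cortex gave 6615 probes, 3417 higher and 3198 lower (2218 and 3342 with median scaling), for 5007 genes and 375 probes without a symbol. Calb2, a calcium-binding protein of granule cells, was higher by 2.88 ± 0.19, the homeobox gene Meis1 by 2.32 ± 0.15 and Btg1 by 2.00 ± 0.13. The kinase Camk2a of forebrain neurons was lower (-3.35 ± 0.24), as were Pld3 (-2.13 ± 0.15) and Plk2 (-1.93 ± 0.14). Cerebellum markers were higher in 13 of 13 (median 2.35, adjusted p = 3.7e-14, but adjusted p = 0.052 with an estimated correlation) and cortex markers lower in 11 of 12 (median -2.47, 1.6e-09, adjusted p = 0.052 with an estimated correlation). Homeostatic microglia genes were lower in 16 of 17 (median -0.66, 5.8e-08, adjusted p = 0.064 with an estimated correlation). Hippocampus against cortex gave 2700 probes, 1332 higher and 1368 lower, with Litaf higher by 0.83 ± 0.11, the kinase Araf by 0.72 ± 0.09 and H2-Ke6 by 0.53 ± 0.07, and Pamr1 lower by 0.96 ± 0.13, Ntm by 0.78 ± 0.10 and Ppp3r1 by 0.75 ± 0.10. Myelin genes were higher in 14 of 14 (median 0.75, 9.1e-15, adjusted p = 0.062 with an estimated correlation), choroid plexus genes in 12 of 12 (median 1.23, 7.65e-14, adjusted p = 0.062 with an estimated correlation), and cortex markers lower in 10 of 12 (median -0.84, 6.25e-07, adjusted p = 0.062 with an estimated correlation).

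Of the arrays whose markers went against their region label, 5 were left out in the fits described above. The arrays labelled cerebellum of Het replicate 4 and KO replicate 1 at 2 months had mean cerebellum markers of 7.66 and 7.73, where 29 other cerebellum arrays had 9.91 to 11.2. Pcp2, a gene of Purkinje cells, stood at 5.95 and 6.17 there (12.3 to 13.5 in the others), and Cdhr1 and S100a5, genes of the olfactory bulb, at 12.01 and 12.56 and at 10.95 and 11.33 (at most 7.90 and 7.04 in the others). Arrays labelled cortex of the same 2 animals (there Het 4 and KO 2) had Pcp2 at 11.7 and 11.5 (33 others at most 9.39). Their cerebellum markers were 9.46 and 9.57 (at most 8.56). The array labelled cerebellum of WT replicate 4 at 2 months had cortex markers at 8.77 (at most 8.33 in the others), and, labelled male, Xist at 8.22 beside Eif2s3y at 8.86. The array labelled hippocampus of Het replicate 1 at 2 months had hippocampus markers at 8.05, below every cortex array (8.19 to 8.73), and cortex markers at 9.44. It was left out only in the fits without each array in turn, where limma called 0 probes in Het hippocampus at 2 months. The 3 arrays of KO replicate 2 at 9 months, labelled male, had Xist at 8.81 to 9.59 and Eif2s3y at 6.05 to 6.14, where the 54 male arrays of undoubted region had at most 7.31 and at least 8.14.

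**Figure D5:**
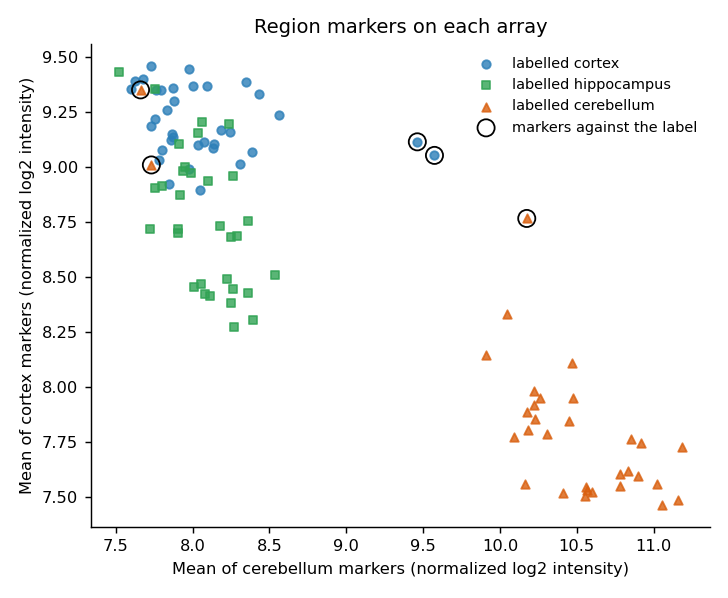
Mean log2 level of the cerebellum markers against that of the cortex markers in each of the 99 arrays, by labelled region; the 5 arrays left out as of doubtful region are circled. Those labelled cerebellum with the lowest cerebellum markers stood at 7.66 and 7.73.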

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

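Chosen only after the result was seen were the tests of a carried chromosome segment, of microglia of the same kind, of blood and meninges, of gene dose, of slides and of sex in cerebellum at 6 months, and of cerebellum markers as a covariate, with or without the doubtful arrays, whose fits were added then. The rules for an array far from its group, for differences between regions and ages, and for other groupings of the same arrays were set before.

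Genes on chromosome 11, which holds Grn, changed in KO beyond their share, 27 of 778. Slide differences as the whole cause were argued against, because 70.4% of them (19 of 27) kept their call with slide as a fixed block and their median size went from 0.38 to 0.40. These 27 include Gfap, also a gene of the glial response. A chromosome segment of another strain carried along with the mutation is a candidate explanation: in 2-month animals, with separate WT arrays for each genotype, Het showed 0.333 of the KO effect (0.233 to 0.441 over 12 divisions of WT), although called genes on other chromosomes gave 0.349 (0.165 to 0.585), so this share does not single it out. Probe binding altered by a strain variant may add to it, since further probes of 5 called genes kept a median of 0.211 of the change (-0.574 to 1.20), against 0.732 for 12 genes elsewhere (-0.352 to 1.01). An effect of Grn loss on its neighbours was not tested and stays open.

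Microglial, complement and lysosomal genes were higher in KO. Slide differences as the whole cause were argued against by a median of 0.207 for activated microglia with slide as a fixed block, beside 0.23 without it. More microglia of the same kind alone was argued against: the activated score exceeded the homeostatic by 0.219 ± 0.0450 in KO against WT. Over all ages the Het activated score, -0.268 ± 0.0384 from the midpoint of KO and WT, argued against a response graded by gene dose. At the youngest age the Het share of 0.349 given above for other chromosomes leaves dose open. Blood or meninges in the samples could not be excluded: their score differences were -0.257 and 0.0284, but the upper bounds of 0.164 and 0.146 lay above the 0.116 that would matter. A change of microglial state in KO remains a hypothesis.

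In KO cerebellum at 6 months 359 probes changed, against 3 at 2 months and 7 at 9 months. Less cerebellar tissue in KO replicates 1 and 3 may account for it: their cerebellum markers stood at 10.2 and 9.91 and their myelin genes at 11.1, against 11.02 and 10.36 in replicate 2 and 10.9 to 11.2 and 10.6 to 10.7 in WT, and with the doubtful arrays left out the markers as a covariate took the count from 556 to 1 (median change 0.734 to 0.505, SE 0.184 to 0.193). With all arrays the covariate left 549, which by the rule written before that fit was run would have counted against it, but that test was void because groups with doubtful arrays held 88.8% of the marker spread within groups. The sex of the WT animals, all female at 6 months, stayed open. Without the sex covariate the median change was 0.622 (SE 0.185) and the count 1. The probes were chosen in the fit with it, so this cannot decide. Slides could not be told apart from KO, since 1 slide held both genotypes; with slide as a fixed block the median change was 0.635 (from 0.739, SE 0.186 to 0.214) and the count 1.

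Of 117 groups and measures tested, 8 held an array far from the others, and chance gives about 1 in 20. Cerebellum markers stood at 7.66 in the array labelled cerebellum of Het replicate 4 at 2 months (others 10.05 to 10.48, n = 5) and at 7.73 in that of KO replicate 1 (others 10.19 to 10.45, n = 5). The latter array had choroid plexus genes at 7.09 (others 8.23 to 8.34) and cortex markers at 9.01 (others 7.81 to 7.92). In cerebellum of WT at 2 months, replicate 3 had myelin genes at 11.33 (others at most 11.01, n = 4) and replicate 4 cortex markers at 8.77 (others 7.89 to 7.99, n = 4). Hippocampus markers stood at 8.19 in cortex of WT replicate 6 at 2 months (others 8.41 to 8.50, n = 6), and activated microglia genes at 9.32 in hippocampus of KO replicate 3 at 2 months (others 8.78 to 8.93, n = 5).

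The effect of KO on a list differed between ages or regions in 12 of 42 tests with the preset correlation, and in 0 of these 12 with an estimated correlation. The difference between 9 and 2 months in cortex was 0.188 for activated microglia (adjusted p = 0.00058, adjusted p = 0.154 with an estimated correlation), 0.192 for complement (0.0043, adjusted p = 0.154), 0.0545 for lysosome (0.038, adjusted p = 0.275), 0.0724 for reactive astrocyte (0.017, adjusted p = 0.154) and -0.0779 for myelin (0.038, adjusted p = 0.502). In hippocampus it was 0.155 for activated microglia (0.0154, adjusted p = 0.540), 0.253 for complement (0.0154, adjusted p = 0.477) and 0.0871 for myelin (0.035, adjusted p = 0.811). In cerebellum it was 0.223 for activated microglia (3.2e-08, adjusted p = 0.109), 0.409 for complement (0.0012, adjusted p = 0.237) and 0.235 for reactive astrocyte (0.0205, adjusted p = 0.176). Homeostatic microglia genes differed by -0.131 between the KO effects in cortex and cerebellum (0.00089, adjusted p = 0.881).

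Groupings of the same arrays, the real one included, were counted, 100 for each comparison named first. Chance was excluded for KO against WT over all regions (2 of 100 groupings gave as many as 85, highest other 223), Het against WT (3, highest other 24, real 19), KO against Het (2, 281, 135), Het cortex over all ages (4, 411, 4), KO cortex at 2 months (4, 796, 15), KO cerebellum over all ages (1, 7, 16) and Het cerebellum over all ages (4, 2, 1). The share was likewise under 0.05 for 9 against 2 months in cortex (1, 2683, 8497), hippocampus (1, 908, 6910) and cerebellum (1, 2, 7586) and for cerebellum against cortex (1, 4384, 6615). It was 0.05 or more for KO cortex over all ages (5, 403, 25) and Het cortex at 2 months (16, 9, 1). So it was at 2 months for KO hippocampus (9, 499, 7), Het hippocampus (23, 498, 1) and KO cerebellum (10, 196, 3). It was also so for hippocampus against cortex (7, 3403, 2700). For counts of 0 the groupings decide nothing, since each gives at least 0. Why some groupings gave several times the real count was not tested.

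With 3 arrays against 3 there are 10 groupings, too few for a share under 0.05. KO gave 1 probe in cortex at 6 months (2 of 10 groupings as many, highest other 6), 7 at 9 months (1 of 10, highest other 2), 4 in hippocampus at 9 months (1 of 10, highest other 1), 359 in cerebellum at 6 months (1 of 10, highest other 0) and 7 at 9 months (1 of 10, highest other 0). Het gave 1 in cortex at 9 months (2 of 10, highest other 1) and 1 in cerebellum at 9 months (1 of 10, highest other 0). Hippocampus over all ages, at 6 months and between 9 and 6 months had no such count, because WT at 6 months had 2 arrays.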

How the results depend on the processing

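Fits without doubtful arrays or the animal of doubtful sex, or with the cerebellum markers, were chosen after the data were seen, all others before. Months are written mo where short. Values below are followed by the reported value in parentheses, counts are probes called by limma, Grn is listed where its call changed, and the cause of a change was not tested unless stated. Signal over background set a limit, since the median of the array medians was 90.1 at 2 months and 254 at 6 and 9 months. Of 47 counts all 47 stayed within 1.5 times the reported ones with no background correction and with the series-matrix values, 44 did without the sex covariate, 43 without the arrays of doubtful region, 43 without the animal of doubtful sex and 41 without a probe filter. The number was 36 with the replicate block, 28 with median scaling, 25 of 44 with slide as a fixed block, 34 of 36 with slide as a random block, 22 of 36 with only the arrays of the contrast, 19 with array weights and 18 with the stricter filter. It was 11 of 11 without the animal block and 6 of 6 for lists without the genes near Grn or with the mean t of all probes. Of 445 gene values, 409 kept direction and call with array weights (30 gained and 4 lost a call), and 441 did with no background correction. Median scaling kept 407 of 442 and slide as a fixed block 375 of 427, with 50 calls lost. Counts of 0 still had 75 to 2032 probes at an unadjusted p under 0.05 under the settings, and 148 to 1680 with an array or animal left out. Slide as a fixed block could not give 9 against 2 months, and slide as a random block was not run over all regions.

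Without a probe filter all probes were tested, so the adjustment ran over more of them. Counts were 11510 for 9 against 2 mo in cerebellum (7586), 2 for Het cerebellum at 2 mo (0), 0 for Het cortex at 2 mo (1), 0 for Het hippocampus at 2 mo (1), 22 for KO cerebellum at 6 mo (359) and 9 for KO cortex at 2 mo (15). Values that reversed were -0.0028 for the complement median in KO over all regions (0.31).

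With the stricter filter fewer probes were tested, which left fewer to call. Counts were 3993 for 9 against 2 mo in cerebellum (7586), 4485 for 9 against 2 mo in cortex (8497), 3809 for 9 against 2 mo in hippocampus (6910), 3690 for cerebellum against cortex (6615), 0 for Het cerebellum at 9 mo (1) and 0 for Het cerebellum, all ages (1). They were also 0 for Het cortex at 2 mo (1), 0 for Het cortex at 9 mo (1), 0 for Het cortex, all ages (4), 0 for Het hippocampus at 2 mo (1), 0 for Het hippocampus, all ages (2) and 10 for Het over all regions (19). This setting gave 1681 for hippocampus against cortex (2700), 47 for KO against Het (135), 0 for KO cerebellum at 2 mo (3), 2 for KO cerebellum at 9 mo (7), 3 for KO cerebellum, all ages (16) and 6 for KO cortex at 2 mo (15). It gave further 0 for KO cortex at 6 mo (1), 3 for KO cortex at 9 mo (7), 10 for KO cortex, all ages (25), 3 for KO hippocampus at 2 mo (7), 0 for KO hippocampus at 6 mo (1) and 2 for KO hippocampus at 9 mo (4). Next came 4 for KO hippocampus, all ages (13) and 20 for KO over all regions (85). Lists called were 4 for Het over all regions (8), 6 for KO against Het (10) and 5 for KO cortex, all ages (10). The sign turned for -0.00673 for the genes near Grn median in Het over all regions (0.00128).

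Array weights raised most of the counts listed. Counts were 9 for 9 against 6 mo in cerebellum (0), 1 for 9 against 6 mo in hippocampus (0), 1 for Het cerebellum at 6 mo (0), 0 for Het cortex at 2 mo (1), 1737 for Het cortex at 6 mo (0) and 2 for Het cortex at 9 mo (1). They were also 53 for Het cortex, all ages (4), 0 for Het hippocampus at 2 mo (1), 1 for Het hippocampus at 6 mo (0), 1 for Het hippocampus at 9 mo (0), 74 for Het over all regions (19) and 4728 for hippocampus against cortex (2700). This setting gave 1 for the KO effect at 9 against 2 mo in cerebellum (0), 210 for the KO effect in cortex against cerebellum (0), 8 for the KO effect in cortex against hippocampus (0), 9 for the KO effect in hippocampus against cerebellum (0), 816 for KO against Het (135) and 1 for KO cerebellum at 2 mo (3). It gave further 3560 for KO cerebellum at 6 mo (359), 21 for KO cerebellum at 9 mo (7), 325 for KO cerebellum, all ages (16), 33 for KO cortex at 2 mo (15), 1584 for KO cortex at 6 mo (1) and 255 for KO cortex, all ages (25). Next came 8 for KO hippocampus at 6 mo (1), 20 for KO hippocampus at 9 mo (4), 35 for KO hippocampus, all ages (13) and 226 for KO over all regions (85). Grn stood at -0.97 for Het cerebellum at 6 mo (-0.77), -0.39 for Het cortex at 6 mo (-0.38) and -1.11 for Het hippocampus at 9 mo (-1.13). Direction changed in 0.11 for Sostdc1 in KO over all regions (-0.0856), 0.10 for Ttr in KO over all regions (-0.13), 0.00835 for the myelin median in KO against Het (-0.0388), 0.0584 for the myelin median in KO cerebellum, all ages (-0.0591) and 0.00379 for the myelin median in KO cortex, all ages (-0.0292).

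Median scaling replaced quantile normalization. Counts were 4 for 9 against 6 mo in cerebellum (0), 2 for 9 against 6 mo in cortex (0), 2 for 9 against 6 mo in hippocampus (0), 0 for Het cortex at 2 mo (1) and 0 for Het cortex at 9 mo (1). They were also 0 for Het hippocampus at 2 mo (1), 1 for Het hippocampus at 6 mo (0), 9 for Het hippocampus at 9 mo (0), 41 for Het over all regions (19) and 1772 for hippocampus against cortex (2700). This setting gave 2 for the KO effect at 9 against 2 mo in cerebellum (0), 1 for the KO effect at 9 against 2 mo in cortex (0), 207 for KO against Het (135), 1 for KO cerebellum at 2 mo (3) and 169 for KO cerebellum at 6 mo (359). It gave further 26 for KO cortex at 2 mo (15), 3 for KO cortex at 6 mo (1), 6 for KO hippocampus at 6 mo (1) and 135 for KO over all regions (85). Grn stood at -1.15 for Het cortex at 9 mo (-1.14). Turned in sign were 0.00859 for Axin2 in KO over all regions (-0.0496), 0.00342 for Cox7c in KO against Het (-0.0437), 0.00859 for Reln in KO over all regions (-0.0712), 0.00892 for the myelin median in KO against Het (-0.0388) and 0.0751 for the myelin median in KO cortex, all ages (-0.0292).

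With only the arrays of the contrast the spread came from fewer arrays. Counts were 1 for 9 against 6 mo in hippocampus (0), 0 for Het cerebellum at 9 mo (1), 0 for Het cortex at 2 mo (1), 9 for Het cortex at 6 mo (0) and 0 for Het cortex at 9 mo (1). They were also 0 for Het hippocampus at 2 mo (1), 1 for Het hippocampus at 6 mo (0), 11 for KO cerebellum at 6 mo (359), 11 for KO cerebellum at 9 mo (7) and 9 for KO cortex at 2 mo (15). This setting gave 3 for KO cortex at 6 mo (1), 3 for KO cortex at 9 mo (7), 0 for KO hippocampus at 6 mo (1) and 2 for KO hippocampus at 9 mo (4). Grn stood at -1.27 for Het cerebellum at 9 mo (-1.27), -1.14 for Het cortex at 9 mo (-1.14) and -3.24 for KO hippocampus at 6 mo (-3.29). The reversed values were -0.0111 for the genes near Grn median in KO hippocampus, all ages (0.00207).

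The replicate block used the replicate numbers of the labels, which did not pair animals: the median residual correlation was 0.0101 for the same number and 0.00611 for different numbers. With this block counts were 1 for 9 against 6 mo in hippocampus (0), 0 for Het cortex at 2 mo (1), 0 for Het cortex at 9 mo (1), 0 for Het hippocampus at 2 mo (1), 1 for Het hippocampus at 6 mo (0) and 1 for KO cerebellum at 2 mo (3). The block also gave 61 for KO cerebellum at 6 mo (359), 4 for KO cerebellum at 9 mo (7), 4 for KO cortex at 9 mo (7), 3 for KO hippocampus at 6 mo (1) and 2 for KO hippocampus at 9 mo (4). Grn stood at -1.14 for Het cortex at 9 mo (-1.14). Going the other way were -0.00696 for the genes near Grn median in KO hippocampus, all ages (0.00207).

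Slide as a fixed block compared arrays within slides, which leaves fewer of them to compare. Counts were 0 for Het cerebellum at 9 mo (1), 0 for Het cortex at 2 mo (1), 0 for Het cortex at 9 mo (1), 10 for Het cortex, all ages (4), 0 for Het hippocampus at 2 mo (1) and 0 for Het hippocampus, all ages (2). They were also 9 for Het over all regions (19), 1 for KO cerebellum at 6 mo (359), 3 for KO cerebellum at 9 mo (7), 3 for KO cerebellum, all ages (16), 7 for KO cortex at 2 mo (15) and 8 for KO cortex at 6 mo (1). This setting gave 0 for KO cortex at 9 mo (7), 9 for KO cortex, all ages (25), 0 for KO hippocampus at 6 mo (1), 0 for KO hippocampus at 9 mo (4), 1 for KO hippocampus, all ages (13) and 45 for KO over all regions (85). Grn stood at -1.26 for Het cerebellum at 9 mo (-1.27), -1.02 for Het cortex at 9 mo (-1.14), -0.68 for Het cortex, all ages (-0.71) and -0.71 for Het hippocampus, all ages (-0.90). It stood at -3.03 for KO cortex at 9 mo (-3.18), -3.14 for KO hippocampus at 6 mo (-3.29) and -2.66 for KO hippocampus at 9 mo (-3.28). Lists called were 6 for KO cortex, all ages (10). Opposite in sign were 0.0501 for Hba-a1 in Het over all regions (-0.09), 0.0632 for the myelin median in KO cerebellum, all ages (-0.0591) and 0.16 for the myelin median in KO cortex, all ages (-0.0292). Slide was also a random block. Counts were 0 for Het cortex at 9 mo (1) and 4 for KO cortex at 9 mo (7). Grn stood at -1.14 for Het cortex at 9 mo (-1.14).

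The sex covariate was then left out. Without it counts were 1 for KO cerebellum at 2 mo (3), 1 for KO cerebellum at 6 mo (359) and 3 for KO hippocampus at 6 mo (1). Changed in direction were -0.0372 for Eif2s3x in Het over all regions (0.0521) and -0.00911 for the genes near Grn median in KO hippocampus, all ages (0.00207). The animal of doubtful sex was left out in another fit. Counts became 0 for Het cortex at 2 mo (1), 3 for KO cerebellum at 9 mo (7), 10 for KO cerebellum, all ages (16) and 1 for KO cortex at 9 mo (7). Changed in sign were -0.000479 for the genes near Grn median in Het over all regions (0.00128).

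The 5 arrays of doubtful region were left out in 1 fit. Counts without them were 1 for Het cerebellum at 2 mo (0), 0 for Het cortex at 2 mo (1), 1 for the KO effect in hippocampus against cerebellum (0) and 556 for KO cerebellum at 6 mo (359). Grn stood at -0.92 for Het cerebellum at 2 mo (-0.75). Reversal gave 0.0142 for the myelin median in KO cerebellum, all ages (-0.0591). The cerebellum markers were used as a covariate with all arrays. This gave 549 for KO cerebellum at 6 mo (359). The opposite sign came with 0.0295 for the myelin median in KO cerebellum, all ages (-0.0591). The same covariate was fitted without the doubtful arrays. Counts with it were 1 for Het cerebellum at 2 mo (0), 6 for KO cerebellum at 2 mo (3) and 1 for KO cerebellum at 6 mo (359). Grn stood at -0.92 for Het cerebellum at 2 mo (-0.75). Lists called were 10 for KO cerebellum, all ages (6).

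An estimated correlation replaced the preset one in the list tests. Lists called were 2 for Het over all regions (8), 5 for KO against Het (10) and 5 for KO cortex, all ages (10).

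Leaving out each array within a region in turn gave these ranges. The spread was pooled over all groups of a region, so arrays outside a contrast moved its count, and a group left with 1 array borrowed its spread from the others. Arrays are named by genotype, age in mo (mo) and replicate number. Of 445 gene values 390 kept direction and call with any array or animal left out, as did 25 of 27 Grn values, 14 of 21 list medians and 20 of 44 counts. 9 against 6 mo in cerebellum (0) ran from 0 to 1, with 1 without Het 9 mo 1. Het cerebellum, all ages (1) ran from 1 to 2, with 2 without Het 6 mo 1 or Het 9 mo 1. Het cortex at 2 mo (1) ran from 0 to 1. It was 1 without KO 2 mo 2, 4 or 5, KO 6 mo 1 or 2, KO 9 mo 3, WT 6 mo 2 or WT 9 mo 1 and 0 without any of the other 27 arrays. Het cortex at 6 mo (0) ran from 0 to 8, with 1 without WT 6 mo 2 and 8 without Het 9 mo 2. Het cortex at 9 mo (1) ran from 0 to 2, with 0 without Het 9 mo 1 or 3 or WT 9 mo 1 or 3 and 2 without WT 9 mo 2. Het hippocampus at 2 mo (1) ran from 0 to 3, with 0 without Het 2 mo 1, 3 or 5 or WT 2 mo 2 or 4 and 3 without WT 2 mo 5. Het hippocampus at 6 mo (0) ran from 0 to 1, with 1 without KO 2 mo 3. Het hippocampus at 9 mo (0) ran from 0 to 1, with 1 without WT 9 mo 2 or 3. The KO effect at 9 against 2 mo in cerebellum (0) ran from 0 to 1, with 1 without KO 2 mo 2 or KO 6 mo 2 or 3. The KO effect at 9 against 2 mo in cortex (0) ran from 0 to 1, with 1 without KO 9 mo 3. KO cerebellum at 2 mo (3) ran from 1 to 5, with 1 without Het 2 mo 2, 3 or 5, Het 6 mo 2, Het 9 mo 3, KO 2 mo 3 or 5, KO 6 mo 1, KO 9 mo 1, WT 2 mo 2, WT 6 mo 2 or WT 9 mo 1, 2 or 3 and 5 without WT 2 mo 3. KO cerebellum at 6 mo (359) ran from 1 to 947, with 1 without KO 6 mo 1 or 3 or WT 6 mo 3, 4 without WT 6 mo 2, 141 without Het 6 mo 3 and 149 without Het 2 mo 3. It was 179 without WT 9 mo 1, 180 without Het 6 mo 2, 195 without Het 2 mo 2 and 196 without WT 9 mo 2. It was 206 without Het 2 mo 5 or Het 6 mo 1, 220 without WT 2 mo 1, 223 without WT 2 mo 4 and 226 without Het 2 mo 1. It was 227 without KO 9 mo 1, 230 without KO 2 mo 5, 557 without KO 9 mo 3 and 810 without WT 6 mo 1. It was 947 without KO 6 mo 2. KO cerebellum at 9 mo (7) ran from 3 to 7, with 3 without KO 9 mo 2 or 3 or WT 9 mo 2 or 3 and 4 without Het 2 mo 3, KO 2 mo 4 or 5, WT 2 mo 3 or WT 6 mo 1. KO cerebellum, all ages (16) ran from 10 to 22, with 10 without KO 6 mo 3, KO 9 mo 2 or WT 9 mo 3. KO cortex at 2 mo (15) ran from 9 to 25, with 9 without KO 2 mo 1 or WT 2 mo 2 and 25 without KO 2 mo 6. KO cortex at 6 mo (1) ran from 1 to 13, with 2 without Het 6 mo 2, KO 6 mo 1, WT 2 mo 1 or WT 6 mo 1 and 13 without KO 6 mo 2. KO cortex at 9 mo (7) ran from 1 to 8, with 1 without KO 9 mo 2 or WT 9 mo 3, 3 without WT 9 mo 1 and 4 without KO 9 mo 1 or WT 9 mo 2. KO hippocampus at 6 mo (1) ran from 1 to 2, with 2 without Het 2 mo 1 or KO 2 mo 3. KO hippocampus at 9 mo (4) ran from 2 to 4, with 2 without Het 2 mo 4, Het 6 mo 3, Het 9 mo 2, KO 2 mo 4, KO 6 mo 2, KO 9 mo 1 or 3, WT 2 mo 1, 2 or 5 or WT 9 mo 2. KO hippocampus, all ages (13) ran from 7 to 18, with 7 without KO 6 mo 3 or WT 6 mo 1 or 2. Grn in Het cortex at 9 mo (-1.14) ran from -1.40 to -0.89, with -1.13 without Het 9 mo 3, -1.09 without WT 9 mo 3, -1.01 without WT 9 mo 1 and -0.89 without Het 9 mo 1. Grn in Het hippocampus at 9 mo (-1.13) ran from -1.41 to -0.84, with -1.41 without WT 9 mo 3.

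Leaving out each animal in turn was done over all regions, the animal named by its replicate number, given by region where it differed. For genes and lists only the ends of the range are given. Atg3 in KO over all regions (-0.21) ran from -0.34 to 0.0904. Gbx2 in KO against Het (-0.0785) ran from -0.16 to 0.0205. Hba-a1 in Het over all regions (-0.09) ran from -0.30 to 0.29. Het over all regions (19) ran from 7 to 26, with 7 without Het 9 mo 1 and 12 without WT 6 mo (hippocampus 1, cerebellum and cortex 2). Hippocampus against cortex (2700) ran from 1635 to 2898, with 1635 without WT 6 mo (hippocampus 1, cerebellum and cortex 2), 1784 without WT 6 mo (hippocampus 2, cerebellum and cortex 3) and 1791 without WT 9 mo 1. KO against Het (135) ran from 84 to 166, with 84 without Het 9 mo 1. Oxt in Het over all regions (0.19) ran from -0.0298 to 0.43. Ppp1r1b in KO over all regions (-0.10) ran from -0.24 to 0.0588. The number of lists in Het over all regions (8) ran from 5 to 11, with 5 without WT 9 mo 1 and 5 without Het 9 mo 1. The genes near Grn median in Het over all regions (0.00128) ran from -0.00889 to 0.0106.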

Other observations

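The test of the other clock genes was chosen after Per1 and Per2 were seen and before its own values were. Beside the microglial lists, KO and Het animals differed in smaller groups. Of the inflammatory cytokine and NF-kB genes 2 were higher in KO than in Het (median 0.02, adjusted p = 0.0040, but adjusted p = 0.088 with an estimated correlation) and of the astrocyte genes also 2 (median 0.03, 0.0072, adjusted p = 0.16 with an estimated correlation). Sfrp1, a secreted inhibitor of Wnt proteins, was higher by 0.37 and Aebp1, a fibroblast gene, by 0.35. The clock gene Per1, which also counts among the immediate early genes, was lower by 0.31 (list median -0.16, adjusted p = 0.00036, but adjusted p = 0.35 with an estimated correlation), and choroid plexus genes had a median of 0.20 (0.0040, adjusted p = 0.56 with an estimated correlation).

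Markers of neighbouring tissue passed with the preset correlation alone in the younger animals. At 2 months KO cortex had medians of 0.62 for thalamus, 0.49 for choroid plexus and 0.45 for cerebellum markers (adjusted p = 0.147, 0.179 and 0.25 with an estimated correlation), and Het cortex had 0.67, 0.46 and 0.42 (0.069 each). Het hippocampus at 2 months had -0.70 for thalamus and -0.85 for choroid plexus (adjusted p = 0.174 each with an estimated correlation). In cerebellum at 6 months interferon response genes were lower in Het, with a median of -0.38 (adjusted p = 5.4e-11, adjusted p = 0.021 with an estimated correlation).

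The hour of dissection could differ between genotypes, as a hypothesis from Per1 (0.20 ± 0.09) and Per2 (0.21 ± 0.07) in Het against WT, neither past the adjusted threshold. The median change of 6 other clock genes was 0.0887, with 4 of 6 higher, which lies between the values set for and against it, so the test did not decide.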
